A study of Mus musculus with 12 samples.

How the data were processed

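Per the labels, liver RNA came from adult C57BL/6 wildtype and Socs2-null mice before (0 h, no operation) and 24 and 36 h after 2/3 hepatectomy, with 2 pools of 3 animals per group and 10 micrograms of total RNA made into biotin-labelled cRNA for each array. The 12 arrays carry 45141 probe sets. The values are the authors' processed intensities on a linear scale, from 1 to 24717, and 12 of them equal 1. Background correction, summarization and normalization are not given in the sources used here. Median intensities were 51.7 and 52.3 (wildtype 0 h), 49.9 and 47.5 (Socs2-null 0 h), 47.3 and 45.7 (wildtype 24 h), 43.5 and 46.8 (Socs2-null 24 h), 49.6 and 47.4 (wildtype 36 h) and 48.3 and 45.9 (Socs2-null 36 h), and no further scaling was applied. In this order the SD of the arrays about their group means was 0.0734, 0.103, 0.115, 0.159, 0.139 and 0.141 on the log2 scale. The sex of the animals and the hour of harvest are not given in the sources used here.

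The platform annotation names 1 gene for 28898 probe sets, several for 551 and none for 15588, and 104 are controls. Of the probe sets with 1 gene, 28689 have a gene identifier in the reference table, and 0 symbols needed updating. A gene was represented by its probe set with the highest mean over all arrays, which left 17097 genes, 7180 of them with several probe sets. Values were tested as log2(value + 16) with no filter. A group was taken as under background when each of its arrays lay under the brightest of 17 tag control probe sets of that array, and folds against it are bounds. Levels of 18 hybridization control probe sets were averaged for each array.

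The tests were chosen before the data were examined. One group-means model with 6 residual degrees of freedom was fitted to all 12 arrays with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend and robust) and statmod 1.5.0 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 12 comparisons were Socs2-null against wildtype at each time and averaged over the times, the 3 pairs of times in each genotype, and the difference between genotypes in the 24 h and 36 h responses. The 32 gene lists, fixed in advance with 557 members, of which the annotation names 492, were tested with camera at a preset correlation of 0.01, adjusted within a comparison, 384 tests in all. They cover growth hormone and STAT5 targets, signalling components, male-biased, female-biased and sex-linked genes, cell cycle, p53, immediate-early and ribosome biogenesis genes, lipid, glucose, urea, bile acid and xenobiotic metabolism, acute phase, stress, interferon, clock, hepatocyte identity and 9 other cell types. Estimated correlations were an alternative, and ranges over alternatives are for the preset one. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

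Genes named were set by a rule. It takes Socs2, then among genes past the threshold whose arrays separate the groups the 10 largest rises and falls (5 for comparisons within Socs2-null liver and between 24 and 36 h), or without such genes the 3 highest and lowest test statistics, and from each list up to 4 members with the smallest p and any growth hormone and STAT5 target. Some were left out for length.

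Alternatives were quantile normalization, centring on array medians, pseudocounts of 1 and 64, dropping the dimmest 25 % or 50 % of genes, the mean of all probe sets of a gene, leaving out cross-hybridizing probe sets, testing all probe sets, plain eBayes, arrayWeights, a replicate block, only the arrays compared, and leaving out each array. The hybridization-control covariate and the average of 0 and 24 h alone were added after the data were seen. In simulated data 50 of 17097 genes changed at each fold. At 24 h 50 %, 92 %, 94 % and 98 % were called at 1.5-, 2-, 3- and 4-fold. The average gave 94 % at 1.5-fold and 100 % above. Each had 10 false calls. Real rates may be lower, as Socs2, at least 5.19-fold lower, was missed at 24 h.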

Results

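Liver RNA of adult wildtype and Socs2-null mice was hybridized to mouse arrays at 0, 24 and 36 h after 2/3 hepatectomy. Socs2 encodes a feedback inhibitor of growth hormone receptor signalling, and the design asks what its loss changes in resting and regenerating liver. Animals at 0 h had no operation and no group a sham one, so time comparisons cannot part liver loss from surgery or harvest hour. Each of the 6 groups held 2 arrays, each of RNA pooled from 3 animals, so n counts pools. So few arrays limit precision for all 17097 genes. Levels are given as mean ± SD intensity with n = 2 pools unless stated, and changes as log2 change ± standard error, with Benjamini-Hochberg adjusted p from limma. Folds come from the log2 change, taken on intensity + 16, or are bounds where marked at least. In brackets on arrays left out, a range covers all alternatives tried. Pearson's r across probe sets ran from 0.985 to 0.996 for the 6 pairs of arrays of a group and from 0.948 to 0.996 for the 60 other pairs.

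By its brightest probe set Socs2 was near background on every Socs2-null array. This probe set, 1 of 4, read 546 and 261 on the wildtype arrays at 0 h, 306 and 116 at 24 h and 264 and 173 at 36 h. On the Socs2-null arrays it read 26.4 and 27.6 at 0 h, 26.6 and 29.5 at 24 h and 28.7 and 23.2 at 36 h, under the brightest of the 17 tag control probe sets of the same array in each case. One other probe set parted the genotypes as well, with 166 ± 81.4 in wildtype and 21.4 ± 0.870 in Socs2-null liver at 0 h, at least 3.90-fold lower. It stood at 109 ± 68.2 against 28.1 ± 13.6 at 24 h (at least 2.68-fold) and 97.9 ± 25.9 against 33.5 ± 17.3 at 36 h, where 1 Socs2-null array read 45.7, over its brightest tag control. Both remaining probe sets gave like levels in the genotypes and check nothing if they lie outside the deleted part, which the sources used here do not give. Within the wildtype livers Socs2 stood at a log2 change of -0.93 ± 0.42 at 24 h (adjusted p = 0.132) and -0.78 ± 0.42 at 36 h (adjusted p = 0.251). Without wildtype 24 h replicate 1 the 24 h value had an adjusted p of 0.0276, in a range of 0.0276 to 0.622 over the alternatives.

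In unoperated liver, Socs2 and the male-biased gene Moxd1 had the largest differences in level between the genotypes among the genes described here. Socs2 was 27.0 ± 0.898 against 403 ± 202 in Socs2-null against wildtype pools, at least 9.47-fold lower (log2 change -3.20 ± 0.42, adjusted p = 0.213). Moxd1, which encodes a copper-dependent monooxygenase-like protein, was 24.1 ± 5.33 against 252 ± 136, at least 5.85-fold lower (-2.65 ± 0.38, adjusted p = 0.213). Zbtb16, a zinc finger transcription factor, had a log2 change of -1.13 ± 0.17 (adjusted p = 0.213). The highest test statistics on the other side belonged to Tcn2, which carries vitamin B12, at 0.69 ± 0.18, to the trefoil peptide gene Tff3 at 0.50 ± 0.13 with 502 ± 79.8 against 347 ± 8.38, and to the serine protease gene Prss30, which was under background in wildtype liver, each with an adjusted p of 0.862. None of the 17097 genes passed the threshold in limma at 0 h, with 847 at an unadjusted p under 0.05 where chance gives 855. That count was 20 without Socs2-null 0 h replicate 1 and 1 without wildtype 24 h replicate 1 or 2, and Socs2 alone had adjusted p of 0.0287 and 0.0253 without wildtype 24 h replicate 1 or 2, in a range of 0.0253 to 0.879.

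Several gene lists, written before the data were examined, leaned the same way in unoperated Socs2-null liver. Of 23 measured acute-phase genes, which encode plasma proteins made in inflammation, 19 had higher means in Socs2-null liver, with a median log2 change of 0.12 (camera adjusted p = 2.37e-08). Their call ended with an estimated correlation between genes (adjusted p = 0.282). Examples were the hepatokine gene Fgl1 at 0.41, the metalloreductase gene Steap4 at 0.56, the metallothionein gene Mt1 at 0.73 and the serum amyloid gene Saa2 at 0.61. Kupffer cell and macrophage markers had a median of 0.14 with 13 of 14 members higher (adjusted p = 0.00116, or adjusted p = 0.776 with an estimated correlation). The perforin-like gene Mpeg1 stood at 0.35 and the complement gene C1qb at 0.23. Components of growth hormone, insulin and cytokine signalling had a median of 0.083 (adjusted p = 0.00886, or adjusted p = 0.282 with an estimated correlation). The growth factor binding protein genes Igfbp1 stood at 0.65 and Igfbp3 at 0.65. Igfbp1 passed the threshold with 1 array left out (0.00796 without Socs2-null 0 h replicate 1, range 0.00796 to 1). Fatty acid oxidation and PPARA targets (median 0.043, adjusted p = 0.0293) and sinusoidal endothelial markers (median 0.089, adjusted p = 0.0376) were called too, with adjusted p of 0.282 and 0.776 with an estimated correlation. No member of these 5 lists passed the test on its own, and adjusted over the list alone 0 members passed in limma as well.

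The 9 measured growth hormone and STAT5 targets were not called at 0 h (adjusted p = 0.463, median -0.11). Igf1, the main growth factor of that axis, stood at -0.072 ± 0.081, Igfals, which carries it in plasma, at -0.11, and the receptor gene Ghr at 0.016. Other members were Cish at -0.58, Socs3 at -0.60 and the transcription factor gene Onecut1 at -0.71. Only the acute-phase call outlasted the loss of each array in turn. The others were lost for signalling components (0.0662 without wildtype 0 h replicate 2 and 0.206 without Socs2-null 0 h replicate 2, range 0.000211 to 0.206), fatty acid oxidation (0.219 without wildtype 0 h replicate 2 and 0.302 without Socs2-null 0 h replicate 2, range 0.0167 to 0.414), macrophage markers (0.215 without wildtype 0 h replicate 2, range 2.67e-06 to 0.215) and endothelial markers (0.0622 without wildtype 0 h replicate 1, 0.215 without wildtype 0 h replicate 2 and 0.454 without Socs2-null 0 h replicate 2, range 0.00866 to 0.454). Quantile normalization ended the calls of signalling components, fatty acid oxidation and endothelial markers, and centring on the array median those of the last pair. The endothelial call ended with a hybridization covariate too (adjusted p = 0.0635).

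At 24 h after hepatectomy 1 gene was higher and 1 lower in Socs2-null liver. Tff3, a secreted peptide gene of mucosal and biliary surfaces, was 329.6 ± 27.6 against 132 ± 6.48, 2.33-fold higher (log2 change 1.22 ± 0.13, adjusted p = 0.0133). Selenbp2, a male-biased gene for a selenium-binding protein, was 2272 ± 93.2 against 4073 ± 60.1, 1.79-fold lower (-0.84 ± 0.090, adjusted p = 0.0133). Socs2 was 28.0 ± 2.06 against 211 ± 134, at least 5.19-fold lower, with an adjusted p of 0.404. In limma 1408 genes had an unadjusted p under 0.05. The count of 2 was 0 (1142 at an unadjusted p under 0.05) without wildtype 0 h replicate 1, 0 (1146 at an unadjusted p under 0.05) without wildtype 0 h replicate 2, 11 without wildtype 24 h replicate 1, 0 (1156 at an unadjusted p under 0.05) without wildtype 24 h replicate 2, 15 without Socs2-null 24 h replicate 1 and 55 without Socs2-null 24 h replicate 2. Tff3 and Selenbp2 were lost with only the arrays of the compared groups (0.489 for each) and without 1 array for Tff3 (0.0627 without wildtype 0 h replicate 1, 0.0623 without wildtype 0 h replicate 2 and 0.227 without wildtype 24 h replicate 2, range 0.0127 to 0.489) and Selenbp2 (0.0627 without wildtype 0 h replicate 1, 0.0623 without wildtype 0 h replicate 2 and 0.194 without wildtype 24 h replicate 2, range 0.00895 to 0.489).

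Genes of lipid synthesis had higher medians and genes of nitrogen metabolism a lower one in Socs2-null liver at 24 h. Of 16 genes of the urea cycle and amino acid catabolism, 15 had lower means, with a median of -0.30 (adjusted p = 8.16e-06, or adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, 2 of them fell, the urea cycle gene Ass1 at -0.71 ± 0.17 and the glyoxylate aminotransferase gene Agxt at -0.49 ± 0.13. Others were Asl at -0.46 and the tryptophan dioxygenase gene Tdo2 at -0.27. Cholesterol synthesis genes had a median of 0.32 with 14 of 17 higher (adjusted p = 0.000409, or adjusted p = 0.578 with an estimated correlation). When adjusted over the list alone 1 rose, the squalene epoxidase gene Sqle at 0.87 ± 0.22, with the regulator gene Srebf2 at 0.42. Fatty acid synthesis genes had a median of 0.28 (adjusted p = 0.00187, or adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 4 of these rose, the elongase gene Elovl6 at 1.37 ± 0.24, Acly, which makes cytosolic acetyl-CoA, at 0.93, the glucose-responsive factor gene Mlxipl at 0.77 and the acyltransferase gene Dgat2 at 0.37. Without Socs2-null 24 h replicate 2, Elovl6 (adjusted p = 0.0394, range 0.0394 to 0.911) and Mlxipl (adjusted p = 0.0394, range 0.0394 to 0.932) passed over all genes.

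Male-biased genes had a median of -0.20 with 12 of 14 lower at 24 h (adjusted p = 0.000806, or adjusted p = 0.305 with an estimated correlation). Adjusted over the list alone, Selenbp2 and the peroxisomal coenzyme A hydrolase gene Nudt7, at -0.61 ± 0.10, fell. The steroid dehydrogenase gene Hsd3b5 stood at -1.09 and Moxd1 at -0.93. Immediate-early genes, the first transcription factors made after a stimulus, had a median of -0.59 with 11 of 12 lower (adjusted p = 0.0106, or adjusted p = 0.578 with an estimated correlation). Atf3 stood at -1.19, Fos at -1.26 and Ier2 at -0.80. Hepatocyte identity genes (median 0.10, adjusted p = 0.0264), acute-phase genes (median 0.062, adjusted p = 0.0356) and signalling components (median 0.088, adjusted p = 0.0356) were called higher, with adjusted p of 0.497, 0.59 and 0.305 with an estimated correlation. Members were the transcription factor gene Foxa3 at 0.60, the serum amyloid gene Saa3 at 1.96 and the interleukin receptor gene Il6ra at 0.64. Igf1 stood at -0.023 ± 0.081 and Igfals at -0.060, and the growth hormone and STAT5 targets were not called (adjusted p = 0.831). Leaving out 1 array ended the calls of male-biased genes (0.532 without Socs2-null 24 h replicate 2, range 3.84e-09 to 0.532) and immediate-early genes (0.198 without wildtype 24 h replicate 1 and 0.0626 without Socs2-null 24 h replicate 2, range 8.72e-05 to 0.198). Those of hepatocyte genes (0.0834 without wildtype 24 h replicate 2 and 0.443 without Socs2-null 24 h replicate 1, range 0.00625 to 0.443), acute-phase genes (0.455 without wildtype 24 h replicate 2 and 0.325 without Socs2-null 24 h replicate 2, range 0.00151 to 0.455) and signalling components (0.182 without wildtype 24 h replicate 1, 0.0802 without wildtype 24 h replicate 2, 0.0732 without Socs2-null 24 h replicate 1 and 0.112 without Socs2-null 24 h replicate 2, range 0.0105 to 0.182) ended too. The same held for cholesterol synthesis (0.276 without wildtype 24 h replicate 1, range 6.47e-08 to 0.276) and fatty acid synthesis (0.0662 without wildtype 24 h replicate 1 and 0.134 without Socs2-null 24 h replicate 1, range 8.72e-05 to 0.134). Among the 8 lists called at 24 h only the urea cycle list kept its call without each array. Hybridization controls were 0.24 lower on the log2 scale in Socs2-null liver. With their level as a covariate the calls of cholesterol synthesis (adjusted p = 0.0764), immediate-early (0.165) and hepatocyte genes (0.0842) ended. That of signalling components ended under quantile normalization (0.116) and centring (0.0597).

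At 36 h the clock gene Cry1 was higher and Dbp, Nudt7 and Cpt1a were lower in Socs2-null liver. Nudt7 was 1870.4 ± 175 against 4758 ± 326, 2.53-fold lower (log2 change -1.34 ± 0.10, adjusted p = 0.00042), and it passed in each alternative tried. Cpt1a, which brings fatty acids into mitochondria for oxidation, was 1447 ± 116 against 3065 ± 216, 2.11-fold lower (-1.07 ± 0.12, adjusted p = 0.0236). Dbp, a transcription factor gene driven by the clock, was 36.1 ± 4.12 against 179.7 ± 77.4 (-1.85 ± 0.24, adjusted p = 0.0333). Cry1, a repressor of the clock, was 257 ± 32.0 against 114 ± 5.47, 2.10-fold higher (1.07 ± 0.13, adjusted p = 0.027). Socs2 was 25.9 ± 3.90 against 219 ± 63.9, at least 6.31-fold lower, with an adjusted p of 0.236. In limma 1101 genes had an unadjusted p under 0.05. The count of 4 was 1 without wildtype 0 h replicate 1 or 2 or Socs2-null 0 h replicate 1 or 2 or wildtype 36 h replicate 2, 10 without Socs2-null 24 h replicate 1 or 2, 16 without wildtype 36 h replicate 1, 2 without Socs2-null 36 h replicate 1 and 11 without Socs2-null 36 h replicate 2. Calls were lost for Cry1 (0.0868 without wildtype 0 h replicate 1 or 2, 0.0766 without Socs2-null 0 h replicate 1, 0.0768 without Socs2-null 0 h replicate 2, 0.0784 without wildtype 36 h replicate 1, 0.101 without wildtype 36 h replicate 2, 0.0667 without Socs2-null 36 h replicate 1 and 0.075 without Socs2-null 36 h replicate 2, range 0.0112 to 0.253), Cpt1a (0.0836 without wildtype 0 h replicate 1, 0.0842 without wildtype 0 h replicate 2, 0.068 without Socs2-null 0 h replicate 1 or 2, 0.102 without wildtype 36 h replicate 2 and 0.196 without Socs2-null 36 h replicate 1, range 0.00906 to 0.252) and Dbp (0.0836 without wildtype 0 h replicate 1, 0.0842 without wildtype 0 h replicate 2, 0.068 without Socs2-null 0 h replicate 1 or 2, 0.0819 without wildtype 24 h replicate 1, 0.0814 without wildtype 24 h replicate 2, 0.101 without wildtype 36 h replicate 2, 0.293 without Socs2-null 36 h replicate 1 and 0.075 without Socs2-null 36 h replicate 2, range 0.0027 to 0.293). Socs2 passed with 1 array left out (range 0.0147 to 0.589).

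**Figure D1:**
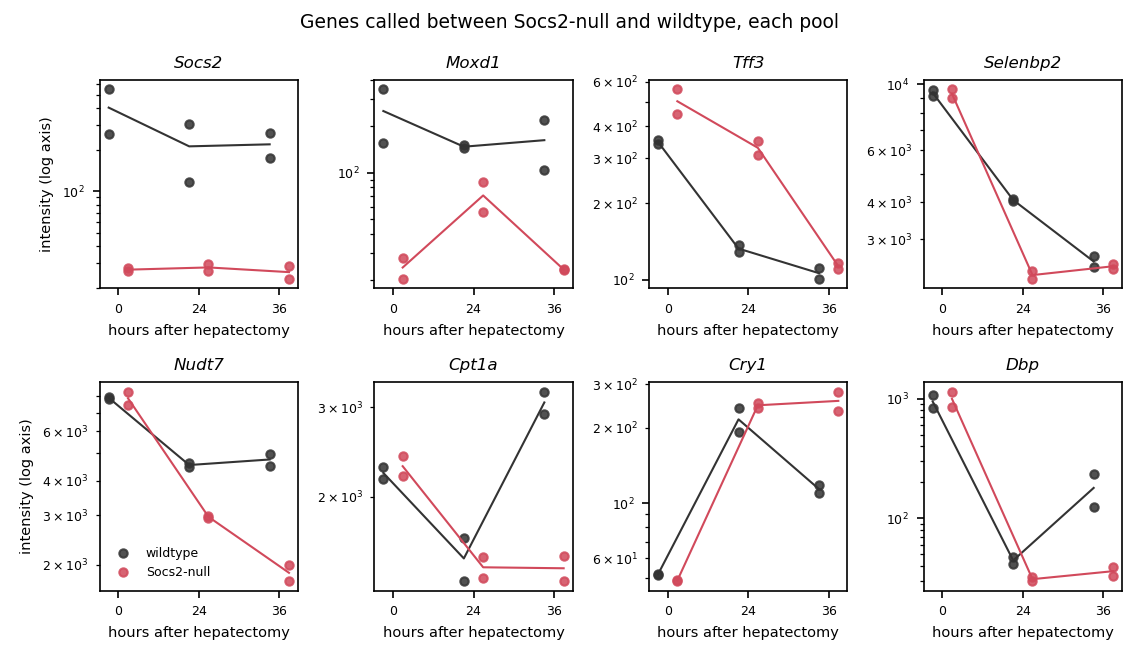
Intensity on a log axis against hours after hepatectomy for 8 of the 9 genes past the threshold in Socs2-null against wildtype liver, all but Fmr1nb. Each point is 1 pool of 3 animals, black for wildtype and red for Socs2-null, set slightly apart along the time axis, and lines join the means of 2 pools. Nudt7 stood at a mean of 1870.4 in Socs2-null against 4758 in wildtype liver at 36 h, and Socs2 stayed under 30 on each Socs2-null array.

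Lists of lipid and bile metabolism were among those called at 36 h. Cholesterol synthesis genes were higher in all 17 measured members, with a median of 0.61 (adjusted p = 3.86e-10, or adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone, 4 of them rose, the squalene synthase gene Fdft1 at 1.14 ± 0.27, the sterol reductase gene Dhcr7 at 1.08 ± 0.27, Msmo1 at 0.80 and Sqle at 0.78. Fatty acid oxidation and PPARA targets had a median of -0.27 with 15 of 19 lower (adjusted p = 4.76e-06), and this call held with an estimated correlation (adjusted p = 0.0446). Cpt1a, Cpt2 at -0.37 and the pantetheinase gene Vnn1 at -1.57 fell when adjusted over the list alone, and the fatty acid carrier gene Fabp1 stood at -0.27. Bile acid genes had a median of -0.43 (adjusted p = 0.00144, or adjusted p = 0.139 with an estimated correlation). Within the list alone, after adjustment, the uptake carrier gene Slco1a4 at -1.44 and the phospholipid exporter gene Abcb4 at -1.01 fell. Fatty acid synthesis genes had a median of 0.21 (adjusted p = 0.00144, or adjusted p = 0.436 with an estimated correlation). Of these, 4 rose adjusted over the list alone, among them the desaturase gene Scd1 at 0.61, Fasn at 0.92 and Acly at 0.95. Xenobiotic metabolism (median -0.088, adjusted p = 0.0067, or adjusted p = 0.172 with an estimated correlation) was called lower with the glucuronosyltransferase gene Ugt2b5 at -0.41 and the nuclear receptor gene Nr1i2 at -0.53. The urea cycle list was again lower (median -0.11, adjusted p = 0.00787, or adjusted p = 0.436 with an estimated correlation). The histidase gene Hal stood at -1.08 and Tdo2 at -0.38. Without 1 array the calls ended for fatty acid synthesis (0.367 without wildtype 36 h replicate 2 and 0.31 without Socs2-null 36 h replicate 1, range 3.76e-06 to 0.367), xenobiotic metabolism (0.2 without Socs2-null 36 h replicate 2, range 0.00138 to 0.2) and the urea cycle (0.878 without wildtype 36 h replicate 1 and 0.0878 without Socs2-null 36 h replicate 1, range 4.99e-05 to 0.878). Fasn passed over all genes (0.039 without Socs2-null 36 h replicate 2, range 0.039 to 0.803).

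Male-biased genes were lower in 13 of 14 measured members at 36 h, with a median of -0.38 (adjusted p = 3.36e-09), and this held with an estimated correlation (adjusted p = 0.0446). Of the members 5 fell adjusted over the list alone, among them Nudt7, Moxd1, at least 4.47-fold, the serpin gene Serpina12 at -1.44 and the complement gene C6 at -0.46. Unfolded protein and integrated stress response genes had a median of 0.50 with 15 of 16 higher (adjusted p = 3.46e-08, or 0.196 with an estimated correlation), and 7 rose adjusted over the list alone. Members were the transcription factor genes Xbp1 at 0.59 and Atf4 at 0.68 and the chaperone genes Pdia4 at 0.63 and Hsp90b1 at 0.34. Ribosome biogenesis genes had a median of 0.42 (adjusted p = 9.02e-06, or 0.513 with an estimated correlation). The assembly factor genes Noc2l stood at 0.47 and Rrs1 at 0.42. Mitotic genes had a median of -0.16 with 36 of 40 lower (adjusted p = 4.76e-06, or 0.391 with an estimated correlation and 0.534 without the dimmest 50 % of genes). The centromere gene Cenpa stood at -0.38 and the anaphase activator gene Cdc20 at -0.41. Calls ended without 1 array for ribosome biogenesis (0.136 without wildtype 36 h replicate 1 and 0.279 without Socs2-null 36 h replicate 1, range 4.35e-09 to 0.279) and mitosis (0.401 without wildtype 36 h replicate 2, range 8.81e-13 to 0.534).

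Acute-phase genes (median 0.13, adjusted p = 0.00144), signalling components (median 0.15, adjusted p = 0.00787) and interferon-stimulated genes (median 0.14, adjusted p = 0.0083) were called higher at 36 h, with adjusted p of 0.436, 0.139 and 0.436 with an estimated correlation. Members were Serpina3n at 0.69, the cytokine receptor gene Il6st at 0.35, the ubiquitin-like protease gene Usp18 at 0.86 and the GTPase gene Igtp at 0.74. Clock genes went both ways and were not called as a list (adjusted p = 0.781, median 0.15, mean -0.018). Adjusted over the list alone, Cry1, Npas2 (at least 2.99-fold, with wildtype levels under background) and 1 other rose, and Dbp, Nr1d2 at -1.52 and 1 other fell. Igf1 stood at 0.10 ± 0.081 and Igfals at -0.22, and the growth hormone and STAT5 targets were not called (adjusted p = 0.943). Without 1 array the calls of acute-phase genes (0.367 without wildtype 36 h replicate 2, range 1.54e-06 to 0.367), signalling components (0.0593 without Socs2-null 36 h replicate 1, range 0.00307 to 0.0764) and interferon-stimulated genes (0.644 without wildtype 36 h replicate 1 and 0.178 without Socs2-null 36 h replicate 2, range 0.000869 to 0.644) ended. Over all genes Npas2 (range 0.00254 to 0.272), Nr1d2 (range 0.00131 to 0.467) and Serpina3n (range 0.0027 to 0.991) then passed.

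Averaged over the 3 times, with n = 6 pools of each genotype, Socs2, Moxd1, Nudt7 and Fmr1nb were lower and Tff3 was higher in Socs2-null liver. Socs2 was 27.0 ± 2.22 against 278 ± 148, at least 6.77-fold lower (log2 change -2.63 ± 0.24, adjusted p = 0.0154). Nudt7 had a log2 change of -0.65 ± 0.057 (adjusted p = 0.00251), Moxd1 of -1.89 ± 0.22 (adjusted p = 0.0294) and Fmr1nb, a germline gene, of -0.48 ± 0.060 (60.7 ± 10.6 against 91.5 ± 17.6, adjusted p = 0.0294). Tff3, named here after its values were seen because its pools did not separate at every time, had a change of 0.60 ± 0.077 (adjusted p = 0.0294). In limma 1750 genes had an unadjusted p under 0.05. The count of 5 was 3 without wildtype 0 h replicate 2 or Socs2-null 36 h replicate 2, 19 without Socs2-null 0 h replicate 1, 1 without Socs2-null 0 h replicate 2, 2 without wildtype 24 h replicate 2 or Socs2-null 36 h replicate 1, 16 without Socs2-null 24 h replicate 1 and 15 without wildtype 36 h replicate 1. Without 1 array the calls ended for Socs2 (0.0662 without Socs2-null 0 h replicate 2, 0.063 without Socs2-null 24 h replicate 2, 0.0571 without Socs2-null 36 h replicate 1 and 0.0695 without Socs2-null 36 h replicate 2, range 0.00114 to 0.0783) and Moxd1 (0.132 without Socs2-null 0 h replicate 2, 0.0941 without wildtype 24 h replicate 1, 0.187 without wildtype 24 h replicate 2, 0.063 without Socs2-null 24 h replicate 2, 0.0625 without Socs2-null 36 h replicate 1 and 0.0846 without Socs2-null 36 h replicate 2, range 0.00238 to 0.202). They also ended for Fmr1nb (0.108 without wildtype 0 h replicate 1, 0.0576 without wildtype 0 h replicate 2, 0.132 without Socs2-null 0 h replicate 2, 0.0695 without wildtype 24 h replicate 1, 0.181 without wildtype 24 h replicate 2, 0.0617 without wildtype 36 h replicate 2, 0.0582 without Socs2-null 36 h replicate 1 and 0.0797 without Socs2-null 36 h replicate 2, range 0.0167 to 0.181) and Tff3 (0.122 without wildtype 0 h replicate 1, 0.214 without wildtype 0 h replicate 2, 0.132 without Socs2-null 0 h replicate 2, 0.0695 without wildtype 24 h replicate 1, 0.187 without wildtype 24 h replicate 2, 0.0779 without wildtype 36 h replicate 2, 0.0582 without Socs2-null 36 h replicate 1 and 0.0797 without Socs2-null 36 h replicate 2, range 0.0116 to 0.214). In the average of 0 and 24 h alone, an alternative chosen after the data were seen, Nudt7 had an adjusted p of 0.365 and Moxd1 of 0.202, against ranges of 0.00119 to 0.365 and 0.00238 to 0.202 over all alternatives.

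In the average, 9 lists were called. Cholesterol synthesis (median 0.22, 16 of 17 higher, adjusted p = 4.67e-08), acute-phase genes (median 0.15, 21 of 23 higher, adjusted p = 5.62e-08) and fatty acid synthesis (median 0.18, adjusted p = 3.22e-05) were higher, with adjusted p of 0.41, 0.33 and 0.41 with an estimated correlation. Sqle stood at 0.55, Fdft1 at 0.49, Acly at 0.61, Fasn at 0.47, Steap4 at 0.68 and the pentraxin gene Apcs at 0.26. Male-biased genes were lower (median -0.28, adjusted p = 7.36e-08, or adjusted p = 0.0698 with an estimated correlation), where Nudt7 and Moxd1 fell over all genes and Selenbp2 as well, at -0.30, adjusted over the list alone. Signalling components (median 0.094, adjusted p = 5.55e-05), the urea cycle list (median -0.15, adjusted p = 0.000535) and macrophage markers (median 0.10, adjusted p = 0.000897) were called higher, lower and higher, with adjusted p of 0.0698, 0.41 and 0.494 with an estimated correlation. Igfbp3 stood at 0.79, Ass1 at -0.34 and Mpeg1 at 0.33. Interferon-stimulated genes (median 0.059, adjusted p = 0.00184) and stress response genes (median 0.083, adjusted p = 0.0021) were higher, with adjusted p of 0.416 and 0.494 with an estimated correlation. Calls ended without 1 array for macrophage markers (0.126 without Socs2-null 24 h replicate 1 and 0.0556 without Socs2-null 36 h replicate 2, range 3.25e-06 to 0.205), interferon-stimulated genes (0.0704 without Socs2-null 24 h replicate 1 and 0.0509 without wildtype 36 h replicate 1, range 1.32e-05 to 0.135) and stress response genes (0.356 without wildtype 24 h replicate 2 and 0.07 without Socs2-null 24 h replicate 2, range 4.68e-06 to 0.914). Steap4 then passed over all genes (0.0358 without Socs2-null 24 h replicate 1, range 0.0358 to 0.475). With the control covariate the macrophage (0.205) and interferon (0.081) calls ended, and that of stress response genes did in the average of 0 and 24 h alone (0.914).

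Growth hormone and STAT5 targets were not called in the average (adjusted p = 0.797, median -0.083), with Igf1 at 0.001 ± 0.047, Igfals at -0.13 and Socs3 at -0.55. Female-biased genes, the counterpart of the male-biased list, had a median of -0.001 over 14 members (adjusted p = 0.797), and 4 sex-linked genes had an adjusted p of 0.918. Neutrophil and monocyte markers (0.968), cholangiocyte markers (0.643), adipocyte markers (0.712), lymphocyte markers (0.918), erythroid genes (0.184) and exocrine pancreas genes (0.607) were not called, each with its adjusted p in brackets. The same held for gluconeogenesis (0.837), clock genes (0.918), G1/S and DNA replication (0.194), CDK inhibitors and p53 targets (0.643), lipid uptake and storage (0.643) and stellate cell and matrix genes (0.918). In the last list the smooth muscle actin gene Acta2 had a change of -0.49 ± 0.078 (adjusted p = 0.0879) and fell adjusted over the list alone, and it passed over all genes with 1 array left out (0.0389 without Socs2-null 24 h replicate 1, range 0.032 to 0.445). Effects of genotype at different times, which share no array, correlated weakly across genes, with Pearson's r of 0.229 for 0 and 24 h, 0.137 for 0 and 36 h and 0.166 for 24 and 36 h. Genes are not independent replicates in such a correlation.

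**Figure D2:**
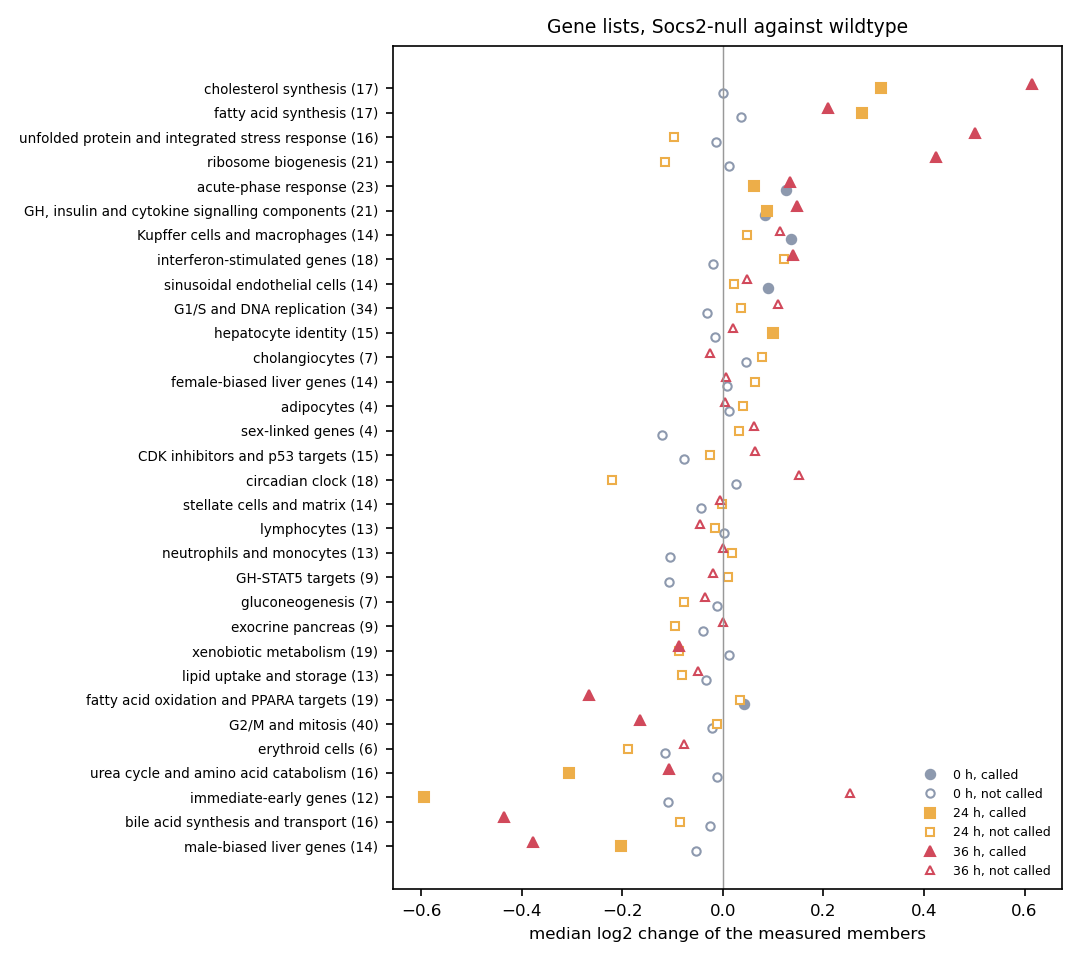
Median log2 change of the measured members of each of the 32 gene lists, Socs2-null against wildtype, at 0 h (circles), 24 h (squares) and 36 h (triangles), with the number of measured members in brackets. Filled marks are lists called by camera with a preset correlation, open marks the others. Cholesterol synthesis went from 0.315 at 24 h to 0.614 at 36 h, and the male-biased genes from -0.202 to -0.377.

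Wildtype liver at 24 h had strongly raised acute-phase genes against unoperated liver, with large rises of single genes outside that list. Lcn2, an iron-scavenging plasma protein gene of the acute phase, rose from 102 ± 26.8 to 7349.7 ± 788 (log2 change 5.98 ± 0.26, adjusted p = 1.52e-06). The cell cycle inhibitor gene Cdkn1a rose to 1173 against 46.2 (4.14 ± 0.34, adjusted p = 0.000116), and the apolipoprotein gene Apoa4 rose as well (4.20 ± 0.23, adjusted p = 5.51e-06). Further large rises were those of the endotoxin receptor gene Cd14 at 4.62, the plasma glycoprotein gene Orm2 at 3.77, the surface antigen gene Ly6d at 3.59, the cytochrome P450 gene Cyp2b10 at 3.46 and the cytokine receptor gene Tnfrsf12a at 3.45. Orm3 (at least 13.5-fold, 572 against 39.3) and the estrogen sulfotransferase gene Sult1e1 (at least 11.1-fold, 472 against 21.4) rose from levels under background, the last with a call lost without 1 array (0.0654 without wildtype 0 h replicate 1, 0.0793 without wildtype 0 h replicate 2 and 0.0669 without wildtype 24 h replicate 1, range 2.38e-05 to 0.0793). The largest falls were those of Dbp at -3.99 ± 0.24 (44.4 ± 3.86 against 950.3 ± 166, adjusted p = 6.1e-06), the uridine phosphorylase gene Upp2 at -3.83 ± 0.65, the transporter gene Abca8a at -3.06 and the steroid dehydrogenase genes Hsd3b5 at -2.97 and Hsd3b2 at -2.58.

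In all 4417 genes changed at 24 h in wildtype liver, 1752 up and 2665 down, and 337 of them rose and 335 fell by 2-fold or more. The count was 1476 without wildtype 0 h replicate 1, 1359 without wildtype 0 h replicate 2, 2082 without wildtype 24 h replicate 1 and 2358 without wildtype 24 h replicate 2. Of the calls 39.7 % were rises, against 65.3 % with each array centred on its median, which moved the median change of all genes from -0.08 by 0.121. Hybridization controls, which are added to each sample in equal amount, fell by 0.21 on the log2 scale between these groups.

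Of 23 acute-phase genes 17 rose, 1 fell and 5 did not pass at 24 h (median 0.74, adjusted p = 1.37e-15, or adjusted p = 0.14 with an estimated correlation). Apcs stood at 2.23 and Serpina3n at 2.40. Ribosome biogenesis genes rose in 15 of 21 members and fell in 1 (median 1.01, adjusted p = 3.59e-09, or adjusted p = 0.28 with an estimated correlation). Bysl stood at 1.31 and the helicase gene Ddx21 at 1.52. Among 34 genes of G1/S and DNA replication 16 rose and 2 fell (median 0.66, adjusted p = 3.59e-09, or adjusted p = 0.338 with an estimated correlation). The helicase subunit gene Mcm6 rose by 2.39, the primase gene Prim1 by 1.73 and the sliding clamp gene Pcna by 1.06, while Mcm10, which loads at replication origins, changed by -2.55. Stress response genes rose in 10 of 16 members (median 0.99, adjusted p = 5.23e-09, or adjusted p = 0.14 with an estimated correlation). The chaperone genes Creld2 stood at 2.87, Hspa5 at 1.16 and Calr at 0.88. Lipid uptake and storage genes rose in 4 of 13 members (adjusted p = 0.0179, or adjusted p = 0.14 with an estimated correlation). The lipid droplet genes Plin5 stood at 1.67 and Plin2 at 1.62. Mitotic genes were not called (adjusted p = 0.618), and of 40 members 1 rose and 5 fell, with the securin gene Pttg1 at -0.96 and Cenpf at -0.73.

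Male-biased genes fell in 9 of 14 members at 24 h (median -0.71, adjusted p = 2.82e-05, or adjusted p = 0.14 with an estimated correlation). Selenbp2 stood at -1.20, Nudt7 at -0.80, Susd4 at -1.64 and C6 at -1.05. Growth hormone and STAT5 targets fell in 5 of 9 members (adjusted p = 0.0287, or adjusted p = 0.14 with an estimated correlation). Igfals stood at -1.20 and Ghr at -0.93, while Igf1 stood at 0.052 ± 0.081 (adjusted p = 0.674). The call of these targets ended with the control covariate (adjusted p = 0.0525, range 0.00333 to 0.0525). Bile acid genes fell in 8 of 16 members (adjusted p = 0.00223, or adjusted p = 0.14 with an estimated correlation). The sterol exporter gene Abcg8 stood at -1.81 and the sterol hydroxylase gene Cyp27a1 at -0.84. Interferon-stimulated genes fell in 10 of 18 members (adjusted p = 0.000259, or adjusted p = 0.182 with an estimated correlation). The chemokine gene Cxcl9 stood at -1.95 and Ifit3 at -0.97. Hepatocyte identity genes fell in 7 of 15 members (adjusted p = 0.000318, or adjusted p = 0.14 with an estimated correlation). The transcription factor gene Cebpa stood at -1.60. Erythroid genes fell in 3 of 6 members (adjusted p = 0.0241, or adjusted p = 0.14 with an estimated correlation). The heme synthesis gene Alas2 stood at -1.21 and the globin gene Hba-a1 at -1.10.

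Further lists were called at 24 h with members in both directions or with calls that rested on 1 array. Xenobiotic metabolism genes fell in 8 of 19 members and rose in 1 (adjusted p = 0.0309, or adjusted p = 0.182 with an estimated correlation). The aldehyde oxidase gene Aox3 stood at -2.12 and Cyp2f2 at -0.70 against Cyp2b10. Fatty acid synthesis genes fell in 7 of 17 members (adjusted p = 0.0309, or adjusted p = 0.529 with an estimated correlation). Elovl6 stood at -1.51 and Dgat2 at -0.84. Cholesterol synthesis genes fell in 5 of 17 (adjusted p = 0.0309, or adjusted p = 0.599 with an estimated correlation). The sterol sensor gene Insig1 stood at -1.47 and Stard4 at -1.41. Fatty acid oxidation genes rose in 7 and fell in 3 of 19 members (adjusted p = 0.0287, or adjusted p = 0.14 with an estimated correlation). The PPARA targets Cyp4a10 stood at 1.88 and Angptl4 at 1.44. Immediate-early genes rose in 2 and fell in 1 of 12 (adjusted p = 0.0241, or adjusted p = 0.476 with an estimated correlation), with Atf3 up at least 3.19-fold. Without 1 array the calls ended for xenobiotic metabolism (0.0715 without wildtype 24 h replicate 1, range 0.00333 to 0.0715), fatty acid synthesis (0.0511 without wildtype 0 h replicate 2 and 0.0648 without wildtype 24 h replicate 1, range 0.00366 to 0.0648) and cholesterol synthesis (0.0648 without wildtype 0 h replicate 1 and 0.332 without wildtype 24 h replicate 1, range 0.000913 to 0.332). Those of fatty acid oxidation (0.0596 without wildtype 24 h replicate 1, range 0.00803 to 0.307) and immediate-early genes (0.075 without wildtype 24 h replicate 1, range 0.00208 to 0.368) ended likewise, and also under quantile normalization and centring on the array median, and the former with the control covariate (0.0525).

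In the remaining lists single genes changed at 24 h without a call for the list. The macrophage receptor gene Marco rose by 2.81 and the lysosomal marker Cd68 by 0.98 in the macrophage list (adjusted p = 0.679). In the clock list 4 genes rose and 5 fell (adjusted p = 0.972). Cry1 stood at 1.77, Per3 at -1.47 and Tef at -1.46. The urea cycle list had 2 rises and 7 falls (adjusted p = 0.237).

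At 36 h wildtype liver still held high levels of most of these genes. Lcn2 stood 5.89 above 0 h on the log2 scale (adjusted p = 1.47e-06), Ly6d 4.14, Cdkn1a 4.13, Apoa4 4.10, Cyp2b10 4.05, Orm2 3.40 and Marco 3.06, and the serine synthesis gene Psat1 rose at least 8.66-fold (399 against 16.9). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -3.37 ± 0.83 (adjusted p = 0.032), the methyltransferase gene Inmt by -4.00 ± 0.72 (adjusted p = 0.0106) and the steroid dehydrogenase gene Hsd3b6 by -2.74 ± 0.38. The sulfotransferase gene Sult2a8 (-3.10), Sucnr1 (-2.71), the carboxylesterase gene Ces1e (-2.60) and Abca8a (-2.41) fell too, and Clec2h fell at least 6.12-fold. Calls were lost without 1 array for Cyp7a1 (0.139 without wildtype 0 h replicate 1 or 2 and 0.142 without wildtype 36 h replicate 2, range 0.00986 to 0.371) and Inmt (0.0639 without wildtype 0 h replicate 1 and 0.0754 without wildtype 0 h replicate 2, range 0.00033 to 0.713).

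The 36 h comparison in wildtype liver called 2597 genes, 973 up and 1624 down, with 178 rises and 265 falls of 2-fold or more. The count was 733 without wildtype 0 h replicate 1, 581 without wildtype 0 h replicate 2 and 1044 without wildtype 36 h replicate 2. The share of rises went from 37.5 % to 53.5 % with arrays centred on their medians. Hybridization controls fell by 0.86 on the log2 scale between these groups. With their level as a covariate, chosen after the data were seen, 523 genes were called, 276 of them among the 2597. The level went from 967 at 0 h to 532 at 36 h, so this covariate follows time and its lower count does not show an effect of hybridization.

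Acute-phase genes rose in 14 of 23 members at 36 h (adjusted p = 1.62e-15, or adjusted p = 0.0773 with an estimated correlation). Male-biased genes fell in 10 of 14 (adjusted p = 1.84e-07, or adjusted p = 0.0773 with an estimated correlation), and Selenbp2 stood at -1.89. Growth hormone and STAT5 targets fell in 4 of 9 (adjusted p = 0.00668, or adjusted p = 0.13 with an estimated correlation). Igfals stood at -1.19 and Igf1 at -0.12 (adjusted p = 0.336). Genes of G1/S and DNA replication rose in 9 and fell in 2 of 34 (adjusted p = 1.21e-07, or adjusted p = 0.433 with an estimated correlation), and both falls were in genes of DNA synthesis, the thymidine kinase gene Tk1 at -1.61 and Mcm10 at -1.92. Fatty acid oxidation genes rose in 7 and fell in 1 of 19 (adjusted p = 2.1e-05, or adjusted p = 0.0743 with an estimated correlation). Cyp4a10 stood at 1.20. Ribosome biogenesis (3 of 21 up, 1 down, adjusted p = 1.35e-05), lipid uptake and storage (4 of 13 up, adjusted p = 0.0186) and erythroid genes (3 of 6 down, adjusted p = 0.022) were called too, with adjusted p of 0.444, 0.163 and 0.173 with an estimated correlation. Plin5 stood at 1.83 and Hba-a1 at -1.07. The mitotic list was called higher (median 0.14, adjusted p = 0.0269, or adjusted p = 0.615 with an estimated correlation), although its 2 members past the threshold fell, Pttg1 at -0.90 and Cenpf at -0.78, which act in chromosome separation. That call was lost without 1 array (0.0876 without wildtype 0 h replicate 1 and 0.68 without wildtype 36 h replicate 2, range 0.000303 to 0.68). Of the 16 lists called in this comparison 8 kept their calls without each array. With the control covariate 7 kept their calls, and those of G1/S (median -0.291, adjusted p = 0.0106, range 1.31e-12 to 0.0106) and mitotic genes (-0.319, adjusted p = 0.0305) turned to lower. CDK inhibitors and p53 targets, among the others, rose in 4 of 15 (adjusted p = 0.0368, or adjusted p = 0.201 with an estimated correlation, and 0.08 without wildtype 36 h replicate 2, range 0.00579 to 0.38). Agxt of the urea cycle list changed by -1.40 and Apob of the hepatocyte list by 1.69.

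Between 24 and 36 h wildtype liver raised 37 genes and lowered 4. Apob, the core protein of very low density lipoprotein, rose from 489 ± 186 to 3025 ± 806 (log2 change 2.62 ± 0.24, adjusted p = 0.00458), and Cpt1a rose by 1.02 ± 0.12 (adjusted p = 0.0234). The 4 genes that fell were Rfxank, a regulator of antigen presentation genes, at -0.96 ± 0.14, Cry1 at -0.83 ± 0.13, Selenbp2 at -0.69 ± 0.090 and 1 gene with levels under background at both times. The count of 41, with 2546 genes at an unadjusted p under 0.05, was 1 without wildtype 0 h replicate 1 or 2, 6 without Socs2-null 0 h replicate 1 or 2, 64 without wildtype 24 h replicate 1, 5 without wildtype 24 h replicate 2, 178 without Socs2-null 24 h replicate 1, 180 without Socs2-null 24 h replicate 2 and 15 without wildtype 36 h replicate 2. Apob kept its call without each array. Calls were lost for Cpt1a (0.0705 without wildtype 0 h replicate 1, 0.0707 without wildtype 0 h replicate 2, 0.139 without wildtype 24 h replicate 2 and 0.0636 without wildtype 36 h replicate 2, range 0.00587 to 0.199) and Rfxank (0.0735 without wildtype 0 h replicate 1, 0.0738 without wildtype 0 h replicate 2, 0.0721 without Socs2-null 0 h replicate 1, 0.0726 without Socs2-null 0 h replicate 2, 0.0766 without wildtype 24 h replicate 1, 0.149 without wildtype 24 h replicate 2, 0.0896 without wildtype 36 h replicate 1 and 0.0636 without wildtype 36 h replicate 2, range 0.012 to 0.321). They were lost as well for Cry1 (0.0969 without wildtype 0 h replicate 1, 0.0968 without wildtype 0 h replicate 2, 0.0787 without Socs2-null 0 h replicate 1, 0.0789 without Socs2-null 0 h replicate 2, 0.114 without wildtype 24 h replicate 1, 0.139 without wildtype 24 h replicate 2, 0.0967 without wildtype 36 h replicate 1 and 0.0786 without wildtype 36 h replicate 2, range 0.0163 to 0.303) and Selenbp2 (0.0705 without wildtype 0 h replicate 1, 0.0707 without wildtype 0 h replicate 2, 0.0504 without Socs2-null 0 h replicate 1, 0.0513 without Socs2-null 0 h replicate 2, 0.139 without wildtype 24 h replicate 2 and 0.0654 without wildtype 36 h replicate 2, range 0.00978 to 0.303). Hybridization controls fell by 0.66 on the log2 scale between the times. With their level as a covariate, which follows time, 0 genes were called in limma, with 1921 at an unadjusted p under 0.05.

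Stress response genes were called lower as a list at 36 than at 24 h, with lower means in 15 of 16 members (median -0.65, adjusted p = 4.77e-08, or 0.546 with an estimated correlation). Ribosome biogenesis (median -0.36, adjusted p = 0.000543) and acute-phase genes (median -0.20, adjusted p = 0.0354) were lower as well, with adjusted p of 0.774 and 0.774 with an estimated correlation. Both calls ended without 1 array (0.185 without wildtype 36 h replicate 1, range 1.08e-06 to 0.185, and 0.225 without wildtype 24 h replicate 1 and 0.448 without wildtype 36 h replicate 2, range 0.000176 to 0.926). With the control covariate ribosome biogenesis (median 0.257, adjusted p = 0.152) and acute-phase genes (adjusted p = 0.926) turned in direction without a call, and the call of the stress response genes ended too (adjusted p = 0.226, range 1.55e-13 to 0.226).

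Socs2-null liver responded at 24 h with many of the same genes. Lcn2 rose by 5.72 ± 0.26, Cdkn1a by 4.76 ± 0.34, Ly6d by 4.35 ± 0.17, Orm2 by 4.25 and Cyp2b10 by 3.54. Upp2 changed by -5.59 ± 0.65, Hsd3b5 by -4.05 ± 0.56, Hsd3b6 by -3.78 and Hsd3b2 by -3.29, and Dbp fell at least 27.1-fold to a level under background. All of these passed in each alternative tried. Of 4146 genes called, 1844 rose and 2302 fell, with 338 rises and 384 falls of 2-fold or more. The count was 2236 without Socs2-null 0 h replicate 1 and 2014 without Socs2-null 0 h replicate 2. The share of rises went from 44.5 % to 60.6 % with arrays centred on their medians. Hybridization controls fell by 0.40 on the log2 scale.

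Acute-phase genes rose in 18 of 23 members in Socs2-null liver at 24 h (adjusted p = 3.61e-13, or adjusted p = 0.0837 with an estimated correlation). Genes of G1/S and DNA replication rose in 19 and fell in 3 of 34 (adjusted p = 3.42e-08, or adjusted p = 0.336 with an estimated correlation). Mcm6 stood at 2.48 and Prim1 at 1.85. Male-biased genes fell in 9 of 14 (adjusted p = 6.01e-06, or adjusted p = 0.0837 with an estimated correlation) and urea cycle genes in 9 of 16 with 1 risen (adjusted p = 0.00149, or adjusted p = 0.233 with an estimated correlation). Selenbp2 stood at -2.02, Nudt7 at -1.40 and Agxt at -1.93. Ribosome biogenesis and stress response genes were called higher, and bile acid, xenobiotic metabolism, interferon-stimulated and erythroid genes lower. In this order these 6 had adjusted p of 0.336, 0.233, 0.0837, 0.15, 0.233 and 0.0837 with an estimated correlation. These 10 lists kept their calls without each array. Hepatocyte identity (adjusted p = 0.0228) and exocrine pancreas genes (adjusted p = 0.045), with adjusted p of 0.233 for each with an estimated correlation, were called lower as well. Their calls ended without 1 array (0.0612 without Socs2-null 0 h replicate 2 and 0.0861 without Socs2-null 24 h replicate 2, range 0.00485 to 0.0861, and 0.0657 without Socs2-null 0 h replicate 2 and 0.101 without Socs2-null 24 h replicate 1, range 0.0278 to 0.237). Igfals changed by -1.15 and Ghr by -0.85, while Igf1 stood at 0.10 (adjusted p = 0.396) and the growth hormone and STAT5 list had an adjusted p of 0.0812.

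At 36 h Socs2-null liver had 1682 genes raised and 1733 lowered against 0 h, 3415 in all, with 306 rises and 349 falls of 2-fold or more. Lcn2 rose by 5.72 ± 0.26, Cdkn1a by 5.12 ± 0.34, Ly6d by 4.38 and Cyp2b10 by 3.90, and Sult1e1 rose at least 42.9-fold (1712 against 34.2). Dbp changed by -4.27 ± 0.24, Hsd3b5 by -4.27 ± 0.56, Upp2 by -4.66, Hsd3b6 by -3.47, Hsd3b2 by -3.33 and Nudt7 by -2.07 ± 0.10 (adjusted p = 1.26e-06). The count was 1727 without Socs2-null 0 h replicate 1, 1563 without Socs2-null 0 h replicate 2 and 2133 without Socs2-null 36 h replicate 1, and with the control covariate 1418, 907 of them among the 3415, beside a fall of the hybridization controls by 0.83 on the log2 scale.

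Male-biased genes fell in 12 of 14 members in Socs2-null liver at 36 h (adjusted p = 3.61e-10, or adjusted p = 0.069 with an estimated correlation). Selenbp2 stood at -1.93 and C6 at -1.52. Acute-phase genes rose in 16 of 23 (adjusted p = 2.25e-11) and ribosome biogenesis genes in 11 of 21 (adjusted p = 7.57e-08), with adjusted p of 0.109 and 0.342 with an estimated correlation. Genes of G1/S and DNA replication rose in 12 and fell in 2 of 34 (adjusted p = 2.72e-06, or adjusted p = 0.511 with an estimated correlation). Mcm6 stood at 2.29 and Mcm10 at -3.27. Growth hormone and STAT5 targets fell in 2 of 9 (adjusted p = 0.0469, or adjusted p = 0.219 with an estimated correlation), which were Igfals at -1.31 and Ghr at -0.97, with Igf1 at 0.046 (adjusted p = 0.734). This last call ended without 1 array (0.0597 without Socs2-null 0 h replicate 1, 0.0527 without wildtype 24 h replicate 1 or 2 and 0.0604 without Socs2-null 36 h replicate 1, range 0.00809 to 0.312). In all, 10 of the 14 lists called kept their calls without each array. With the control covariate 8 kept them, and G1/S genes were called lower (median -0.252, adjusted p = 0.0498, range 5.13e-08 to 0.0498).

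Between 24 and 36 h only Tff3 was called as changed in Socs2-null liver, from 330 ± 27.6 to 113 ± 4.53 (log2 change -1.42 ± 0.13, adjusted p = 0.00552), with 1228 genes at an unadjusted p under 0.05 in limma. These pools did not group by time, so few calls do not show that few genes changed. The count of 1 rose without some arrays, and the call of Tff3 was lost without 1 (range 0.0042 to 0.996). Apob stood at 1.02 and Nudt7 at -0.66. Male-biased genes (median -0.25, adjusted p = 1.72e-05) and fatty acid oxidation genes (median -0.10, adjusted p = 0.0052) were called lower and cholesterol synthesis genes (median 0.51, adjusted p = 2.59e-06) higher, with adjusted p of 0.161, 0.161 and 0.86 with an estimated correlation. These calls ended without 1 array for male-biased genes (range 1.11e-08 to 0.199), fatty acid oxidation (range 0.000338 to 0.193) and cholesterol synthesis (range 3.96e-16 to 0.528), as did the 5 other list calls of this comparison. Hybridization controls fell by 0.44 on the log2 scale, and with their level as a covariate the calls of fatty acid oxidation (0.0949), cholesterol synthesis (0.528) and 3 of the other 5 ended.

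**Figure D3:**
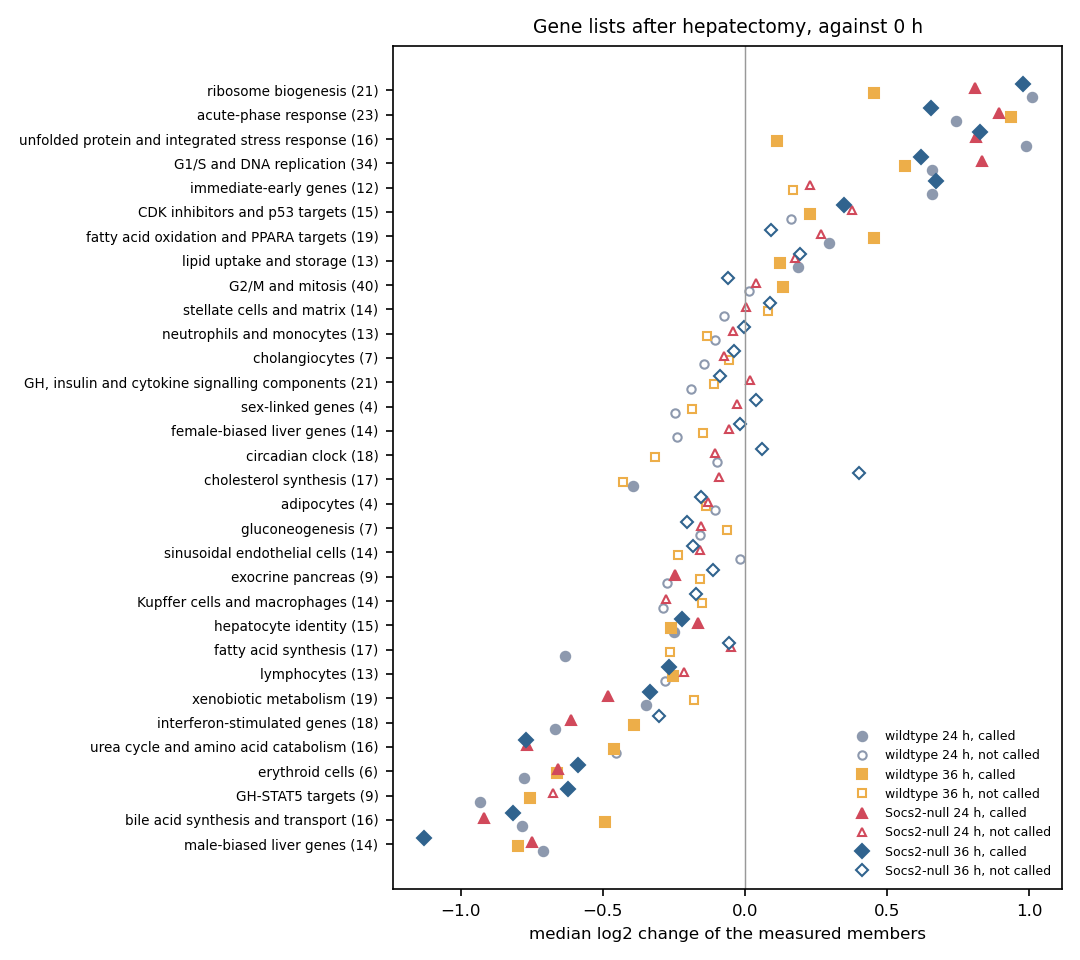
Median log2 change against 0 h of the measured members of each of the 32 gene lists at 24 and 36 h in wildtype and Socs2-null liver, with the number of measured members in brackets. Filled marks are lists called by camera with a preset correlation, open marks the others. Ribosome biogenesis stood at 1.009 in wildtype liver at 24 h, and the male-biased genes were below 0 in each of the 4 comparisons.

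The responses of both genotypes ran in parallel. At 24 h changes correlated across genes with r = 0.888 and a slope of 0.909 for Socs2-null on wildtype, and 1278 genes rose and 1620 fell in both, where independent lists would share 189 and 359, with 0 called in opposite directions in limma. At 36 h r was 0.866 and the slope 1.006, with 816 shared rises and 1055 shared falls against 96 and 165 for independent lists and 2 genes in opposite directions.

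**Figure D4:**
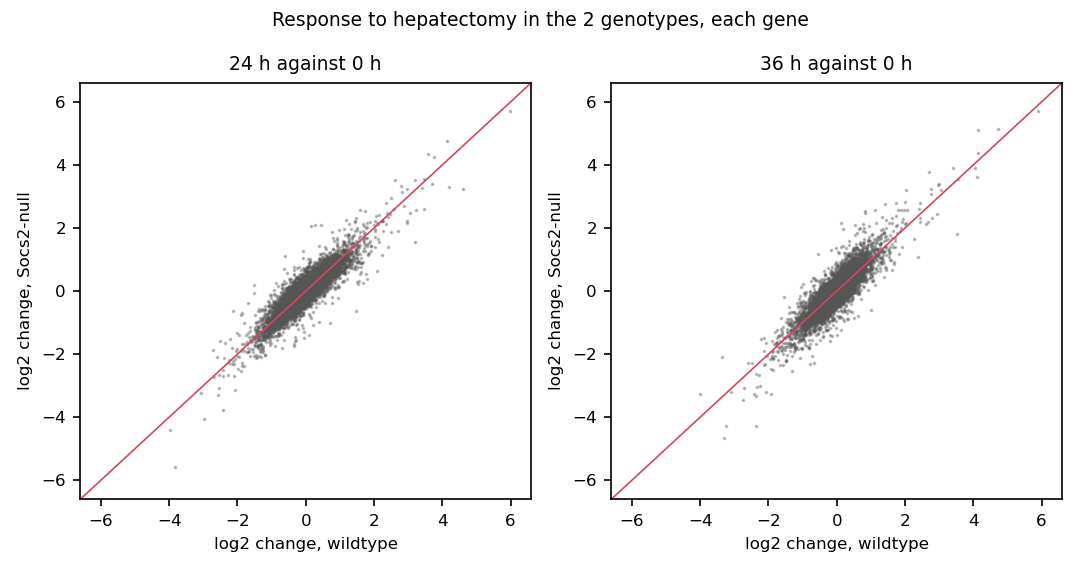
Log2 change of each of 17097 genes after hepatectomy in wildtype liver (horizontal axis) and Socs2-null liver (vertical axis), at 24 h (left) and 36 h (right). Each point is 1 gene and the red line marks equal change. The correlation across genes was 0.888 at 24 h and 0.866 at 36 h.

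A direct test of the difference between genotypes in the 24 h response called no gene in limma, with 646 at an unadjusted p under 0.05. The lowest statistics were those of Selenbp2 at -0.83 ± 0.13 (adjusted p = 0.658), Nudt7 at -0.60 and Ccdc102a at -0.79, and the highest those of Ttc14 at 0.80, Zbtb16 at 1.12 and the phospholipase gene Pla2g2c at 0.70. The count was 12 without Socs2-null 0 h replicate 1, 2 without wildtype 24 h replicate 1 and 6 without Socs2-null 24 h replicate 1. Of 16 urea cycle genes all had a lower change in Socs2-null liver (median -0.29, adjusted p = 8.57e-07, or adjusted p = 0.62 with an estimated correlation). Agxt stood at -0.69 and Ass1 at -0.65. Cholesterol synthesis genes had a higher one in 16 of 17 (median 0.30, adjusted p = 0.00874, or adjusted p = 0.62 with an estimated correlation). Sqle stood at 0.87. The cholesterol call ended without 1 array (0.183 without Socs2-null 0 h replicate 1 and 0.444 without wildtype 24 h replicate 1, range 2.58e-06 to 0.444) and with the control covariate (0.127).

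In the 36 h response the genotypes differed in Nudt7, with a log2 difference of -1.33 ± 0.14 (adjusted p = 0.0168), beside 640 genes at an unadjusted p under 0.05 in limma. Its call was lost without 1 array (0.286 without wildtype 0 h replicate 1, 0.254 without wildtype 0 h replicate 2, 0.224 without Socs2-null 0 h replicate 2, 0.117 without wildtype 36 h replicate 2 and 0.0716 without Socs2-null 36 h replicate 1, range 0.00402 to 0.324). The count of 1 was 0 (463 at an unadjusted p under 0.05) without wildtype 0 h replicate 1, 0 (365 at an unadjusted p under 0.05) without wildtype 0 h replicate 2, 13 without Socs2-null 0 h replicate 1, 0 (454 at an unadjusted p under 0.05) without Socs2-null 0 h replicate 2, 2 without wildtype 24 h replicate 1 or 2 or Socs2-null 24 h replicate 1 or 2 or wildtype 36 h replicate 1 or Socs2-null 36 h replicate 2, 0 (761 at an unadjusted p under 0.05) without wildtype 36 h replicate 2 and 0 (516 at an unadjusted p under 0.05) without Socs2-null 36 h replicate 1. Cpt1a stood at -1.12 ± 0.18, Cry1 at 1.13 ± 0.19 and Dbp at -1.92 ± 0.34, which passed without 1 array (0.0382 without wildtype 36 h replicate 1, range 0.0382 to 1). Fatty acid oxidation and PPARA targets had a lower response in Socs2-null liver (median -0.30, adjusted p = 1.63e-08), the third call that held with an estimated correlation (adjusted p = 0.0164), with Vnn1 at -1.61, Cpt2 at -0.49 and Ppara at -0.60. Of 115 list calls over the 12 comparisons, these 3 held in that way. Cholesterol synthesis (median 0.67, adjusted p = 1.07e-06), stress response genes (median 0.47, adjusted p = 0.000236) and ribosome biogenesis (median 0.41, adjusted p = 0.00422) had higher responses, with adjusted p of 0.458, 0.458 and 0.759 with an estimated correlation, and Fdft1 stood at 1.12. Lower responses were called for male-biased genes (median -0.18, adjusted p = 3.43e-05), mitotic genes (median -0.12, adjusted p = 1.99e-05), xenobiotic metabolism (median -0.18, adjusted p = 0.000142), urea cycle genes (median -0.17, adjusted p = 0.00231) and bile acid genes (median -0.37, adjusted p = 0.0025). With an estimated correlation the adjusted p of these 5 were 0.133, 0.458, 0.112, 0.458 and 0.157. Leaving out 1 array ended the calls of cholesterol synthesis (0.104 without Socs2-null 36 h replicate 2, range 1.07e-15 to 0.104) and ribosome biogenesis (0.65 without wildtype 36 h replicate 1 and 0.697 without Socs2-null 36 h replicate 1, range 9.92e-06 to 0.697). It also ended those of mitotic genes (0.222 without wildtype 36 h replicate 2, range 3.67e-10 to 0.261), urea cycle genes (0.65 without wildtype 36 h replicate 1, range 1.24e-05 to 0.65) and bile acid genes (0.0517 without Socs2-null 0 h replicate 2, range 0.000728 to 0.0517).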

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

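The tests of the clock genes, of the male-biased genes and of 1 pool, the scaling and hybridization were chosen only after the results were seen. Those of other splits of the arrays and of a later course were planned.

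Each of the following was called different between the genotypes in a test of the response itself. At 24 h these were cholesterol synthesis genes (median log2 difference 0.30) and urea cycle genes (-0.29), and both calls were lost (adjusted p = 0.62 with an estimated correlation for each). At 36 h Nudt7 differed by -1.33, and by list medians cholesterol synthesis by 0.67, stress response genes by 0.47, ribosome biogenesis by 0.41, bile acid genes by -0.37, fatty acid oxidation by -0.30, male-biased genes by -0.18, xenobiotic metabolism by -0.18, urea cycle genes by -0.17 and mitotic genes by -0.12. Of these 9 lists only fatty acid oxidation kept its call (adjusted p = 0.0164 with an estimated correlation), and the other 8 had adjusted p of 0.112 to 0.759 there. Among 16139 probe sets that carry no single gene and were not used in the comparisons, limma called 3 at 0 h, 4 at 36 h and 1 in the average, and 0 at 24 h with 1551 at an unadjusted p under 0.05.

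For the 5 genes called in the average over the times, 100 splits of the arrays within times were drawn of 108. The real split called 5 and the highest of the others 1. The 5 include the deleted gene Socs2, which only the real split parts in full, so chance stays open for the other genes. The count was 1 with arrayWeights.

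Clock genes at 36 h parted the genotypes, with the index of evening minus morning genes lower by -1.46 ± 0.32 in Socs2-null liver. A lower index carried at every time is argued against by 0 h, where the difference of 0.21 ± 0.32 lay above 50 % of that at 36 h by 0.94 ± 0.354, while 24 h had -0.66 ± 0.32. Without Dbp, Nr1d2, Cry1 and Npas2 the index at 36 h was still lower, by -0.85 ± 0.35. That difference rests largely on wildtype replicate 2, at -0.17 against -1.13 in wildtype replicate 1 and -1.36 and -1.64 in Socs2-null liver. Another hour of the day at the Socs2-null harvest may still account for the pattern. With the genotypes' harvest hours not given, a shift in phase, which need not lower the index at each hour, and a slower or faster clock after surgery stay open, untested.

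Lower male-biased genes in Socs2-null liver argue for neither female animals nor 1 array. Female animals would raise the female-biased genes, whose median in the average was -0.001, and without any 1 array the highest adjusted p of the male-biased genes was 4.9e-05, although the call was lost otherwise (adjusted p = 0.0698 with an estimated correlation). A change of growth hormone signalling through STAT5 may be the source, but its targets had a median of -0.08 with members on both sides, such as Socs3 at -0.55, so this cannot be told apart from no change.

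Of the 13 lists called at 36 h, 2 held with an estimated correlation and 5 without each array in turn, wildtype arrays included. Without the Socs2-null pool whose loss ended more calls 9 held, under either scaling 13, which argues against pool or scaling as the whole cause. With the hybridization covariate 13 held too, but it could hardly act, as the controls differed by -0.02 on the log2 scale. A later course of the same response in Socs2-null liver would turn the genotype difference against the wildtype change from 24 to 36 h. With no array shared, the correlation over 257 genes was -0.19, close to the limit of -0.2 set in advance, so it cannot be told apart. Harvest hours stay open too.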

How the results depend on the processing

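The hybridization covariate and the average of 0 and 24 h alone were chosen after the data were seen. Of the values named for single genes, 126 of 198 past the threshold in hepatectomy comparisons passed in every alternative, and 1 of 12 in genotype comparisons, Nudt7 at 36 h. Over all alternatives 9169 values of single genes kept their direction and side of the threshold, 310 became weaker, 45 stronger and 15 moved. For lists 3012 were the same, 311 weaker, 3 stronger and 12 reversed. With an estimated correlation 3 of 115 list calls held, and the other alternatives gave 102 to 127.

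Counts of called genes moved by over 1.5 times as follows. Testing all probe sets gave 3 at 0 h (against 0), 10 at 36 h (4), 8921 for wildtype 24 h against 0 h (4417), 5202 for 36 h against 0 h (2597) and 461 for 36 h against 24 h (41), and in Socs2-null liver 8420 (4146), 7116 (3415) and 2 (1), and 2 for the 36 h response difference (1). More probe sets are tested there. Only the arrays compared gave 0 at 24 h (2), 13 (41) for wildtype and 0 (1) for Socs2-null 36 h against 24 h, 2440 (4146) and 2 (1) for the 36 h response difference, from fewer arrays; the average has no such value. The covariate gave 13 (4) at 36 h, 30 (5) in the average, 523 (2597), 0 (41), 1418 (3415) and 0 (1) in the time comparisons that hold 36 h. In the average, pseudocount 64 gave 3 (5), arrayWeights 1, and the average of 0 and 24 h alone 3. Centring gave 26 (41) for wildtype 36 h against 24 h. For the 36 h response difference centring, the mean of probe sets and plain eBayes gave 0 (1). Apart from those named, the cause was not tested.

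Replicate numbers do not pair the arrays. Of 15 pairs of groups 3 had a correlation of deviations over 0.1, in a range of -0.5 to 0.35. The value of -0.5 was that of Socs2-null liver at 24 and 36 h, where pools with opposite replicate numbers went together. A replicate block gave 2 at 0 h (0), 7 at 36 h (4), 3 in the average (5) and 24 (41) for wildtype 36 h against 24 h, and it moved no other count by over 1.5 times.

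Leaving out each array gave 0 to 20 genes at 0 h, 0 to 55 at 24 h, 1 to 16 at 36 h and 1 to 19 in the average. In wildtype liver the range was 1359 to 4946 (24 h), 581 to 3063 (36 h) and 1 to 180 (36 h against 24 h), and in Socs2-null liver 2014 to 4333, 1563 to 3949 and 1 to 8. The response differences ran from 0 to 12 and from 0 to 13. A lone array left in a group is assumed to vary like the other groups.

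Median changes that reversed with the covariate were -0.291 and -0.319 for G1/S and mitotic genes and -0.097 for lymphocyte markers (wildtype 36 h), 0.257 and -0.098 for ribosome biogenesis and acute-phase genes (wildtype 36 h against 24 h), -0.252 for G1/S (Socs2-null 36 h) and -0.016 for acute-phase genes (Socs2-null 36 h against 24 h). Where a median kept its sign, the test's direction turned. Without the dimmest 50 % they were -0.128 for mitotic genes and 0.516 for lymphocyte markers (wildtype 36 h) and 0.518 (Socs2-null 36 h), from fewer members. For Socs2-null 36 h against 24 h, G1/S ran from -0.466 to 0.111 without 1 array, reversed without Socs2-null 24 h replicate 1, and fatty acid synthesis from 0.005 to 0.336, reversed in its test without Socs2-null 36 h replicate 1, and the cause was not tested. Signal over background limits Socs2, Moxd1 and other dim genes, whose low group lies at the control level, so that their folds are bounds. Without the dimmest 50 % of genes 2 genotype list calls ended at 0 h, 4 at 24 h, 3 at 36 h, 2 in the average and 1 in the 36 h response difference.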
